A study of Mus musculus with 28 samples.

How the data were processed

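RNA sequencing of 28 mouse libraries in 9 groups was analysed from the deposited processed tables. Per the labels, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq kit. The authors estimated expression with RSEM 1.2.4 on the mm10 genome, per the submitters' processing notes. The deposited tables give expected counts, which are RSEM's estimated counts per gene without normalization. They also give TPM (transcripts-per-million) and FPKM (length-scaled fragments-per-million), and per the file headers the length and effective length of each gene in each library. FPKM was not used. The aligner and the annotation release are not stated, and the gene identifiers are those of Ensembl. The series-wide count table holds 31673 genes, and the tables of single samples hold 32406. The 733 genes found only in the per-sample tables hold 0.114 to 0.606% of the counts of a library, and the largest difference between the tables for shared genes was 0. Of the identifiers, 31426 were found in GENCODE M21, 30660 with the same symbol, and positions were taken from there.

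Groups and replicates followed the cell type and title in the labels. The source name of the MNF_ciEPC samples reads MEF, in conflict with these fields, and was not followed. The MEF_ciEPC libraries of one numbered series were treated as passages of one culture line, which is a reading of the titles, and were summed to 1 sample each. Counts rounded to whole numbers were fitted with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, TMM scaling, filterByExpr with a minimum count of 10) in 1 fit of 20 samples that held all 9 groups. The common biological coefficient of variation was 0.25 and the prior degrees of freedom were 4.46. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. The difference between the fibroblast sources was tested as an interaction. The passage trend used the 10 MEF_ciEPC libraries one by one, with the series and log2 passage as terms, and calls had no fold minimum.

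Means and SDs are TMM-scaled CPM of the 20 samples, and values of single libraries are scaled over the 28 libraries. A fold is the fitted value where the lower group has more than 3 counts. A group without counts gives a bound against a floor of 3 counts over the group, and 1 to 3 counts give a ratio with its exact 95% counting interval (Clopper-Pearson, on the share of the counts of both groups). Interactions have no such bound, so they are ranked by the fitted value. Similarity is the Pearson correlation of log2 CPM with a prior count of 2.

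The gene lists were 36 sets of textbook markers fixed before the data were examined. They cover fibroblasts, epithelium, endoderm, mesendoderm, extraembryonic endoderm, pluripotency, hepatoblasts, hepatocyte regulators and functions, other organs and cell types, cell cycle and stress, signalling targets, germline, Hox, imprinted and sex chromosome genes. The list of mitochondrially encoded genes has no members in the tables and was not tested. Each list was tested with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The fry test, which asks whether the genes of a list move on balance one way without comparing them with other genes, was an alternative. Some genes belong to more than 1 list. The genes named were drawn from those picked by a rule fixed before the data were examined. It takes, per comparison, the 6 largest rises and 6 largest falls among called genes with at least 32 CPM in the higher group and libraries that do not overlap, without the last condition for interactions. It adds up to 4 members per list with the smallest adjusted p and 16 lineage genes. Any gene outside the rule is said to be chosen after its values were seen.

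The comparisons, the tests and these alternatives were also chosen before the data were examined. They were RLE scaling, DESeq2 1.42.0, limma on log2(TPM + 1), no low-count filter or a minimum of 50, no fold minimum, a replicate block, the 10 MEF_ciEPC libraries as separate samples or only up to passage 5, only the compared groups in the fit, and leaving out each replicate. Leaving out the library labelled MEF_ciEPC series 2 passage 22 was added after its profile was seen. Where an alternative leaves a group with 1 sample, the spread comes from the other groups. The replicate numbers do not pair the libraries: of 73 pairs of libraries with the same number, 0 had a residual correlation above 0.1 and 1 below −0.1.

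The fit was tested on simulated counts with known changes at the depth and group sizes of the data. For MEF_ciEPC against MEF it recovered 22 of 57 genes changed 2-fold, 67 of 73 at 4-fold and 70 of 70 at 8-fold, with 5 false calls in 15673 genes. For MNF_ciEPC against MNF it recovered 16 of 65, 56 of 66 and 66 of 69, with 9 false calls in 15694. The trend recovered 75 of 90 tested genes at 1.41-fold per doubling of passage and 81 of 81 at 2-fold, the rest of 105 being dropped by the low-count filter. The simulated spread was set by expression level alone, and no simulated library stood apart from its group. In the data some slopes above 1.41-fold were not called, so the simulation overstates what the trend could find. Of 1000 random lists, 13 to 19 had a camera p under 0.05, which does not test genes that vary together.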

Results

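RNA was measured by sequencing in 28 mouse libraries from 9 kinds of cell. The series asks whether chemical treatment alone can turn fibroblasts into cells of the endoderm lineage, and those cells into hepatocyte-like cells. The starting cells were fibroblasts of mid-gestation embryos (MEF, 3 libraries) and neonatal dermal fibroblasts (MNF, 2 libraries). The chemically induced endoderm progenitor cells, called ciEPCs, came from MEF (MEF_ciEPC, 10 libraries) or from MNF (MNF_ciEPC, 2 libraries). The labels of MNF_ciEPC conflict: title, description and cell type name MNF, and the source name reads MEF. All comparisons by origin rest on the cell type. The MEF_ciEPC libraries form 2 series followed over passages, 6 libraries from passage 2 to passage 22 in series 1 and 4 libraries from passage 1 to passage 22 in series 2. Hepatocyte-like cells, called ciHeps, were derived from the ciEPCs of MEF origin (MEF_ciHep, 3 libraries) and of MNF origin (MNF_ciHep, 2 libraries). The reference cells were mouse embryonic stem cells (ESC, 2 libraries), endoderm progenitors derived from mouse embryonic stem cells (ESC_EPC, 2 libraries) and primary adult hepatocytes (pHep, 2 libraries).

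The libraries held 1439670 to 6133147 expected counts. By group the range was 3548977 to 5218402 in MEF, 5273876 to 5394678 in MNF, 1439670 to 3352758 in MEF_ciEPC and 5100676 to 5931683 in MNF_ciEPC. It was 3967519 to 4309990 in ESC_EPC, 2420756 to 6133147 in MEF_ciHep and 1664063 to 3102564 in MNF_ciHep. In the reference cells it was 2010637 to 2745369 in pHep and 2192887 to 6123624 in ESC. The length implied by the deposited lengths and effective lengths, whether of fragments or of reads, fell into classes. It was 74.3 to 74.5 bases in MEF, MNF, MNF_ciEPC and ESC. It was 49.5 to 50.6 bases in MEF_ciEPC, both ciHep groups and pHep and 187 to 196 bases in ESC_EPC. The comparisons of MNF_ciEPC with MNF, of MEF_ciHep with MEF_ciEPC and of each ciHep group with pHep lie within a class, and the others cross classes. The labels do not say that replicates were separate cultures, so every p measures the spread between samples. Expression is given as mean counts-per-million (CPM) ± SD over libraries, or over the 2 series for MEF_ciEPC. Intervals and floors cover counting error only. The rises and falls named in each comparison are from the largest among called genes with at least 32 CPM in the higher group and no overlap between libraries. For gene lists, plain numbers in parentheses after a count are the members called when p is adjusted over the list alone. Positions are on GRCm38.

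Profiles were first compared by the Pearson correlation of log2 CPM across genes, which are not independent replicates. MEF_ciEPC correlated with MNF_ciEPC at 0.927 ± 0.055 (SD over 20 library pairs) and with ESC_EPC at 0.804 ± 0.009. It correlated with ESC at 0.788 ± 0.059 and with MEF at 0.757 ± 0.02. MNF_ciEPC correlated with MNF at 0.712 ± 0.003, and ESC_EPC with ESC at 0.817 ± 0.004. MEF_ciHep correlated with pHep at 0.789 ± 0.011, with MEF_ciEPC at 0.782 ± 0.051 (0.799 ± 0.014 without the library labelled MEF_ciEPC series 2 passage 22) and with MEF at 0.673 ± 0.011. MNF_ciHep correlated with MEF at 0.835 ± 0.021, with MNF at 0.815 ± 0.029, with MNF_ciEPC at 0.802 ± 0.028 and with pHep at 0.731 ± 0.007.

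One library stood apart from its group. The library labelled MEF_ciEPC series 2 passage 22 correlated with the ESC libraries at 0.956 ± 0.003 and with the other 9 MEF_ciEPC libraries at 0.762 ± 0.017. Those 9 correlated with each other at 0.946 ± 0.021 and with ESC at 0.769 ± 0.016. It had 1250 CPM of Pou5f1 and 885 CPM of Nanog, transcription factors that hold cells pluripotent, where the other MEF_ciEPC libraries had at most 0.372 and 0.744 CPM. It had 0.503 CPM of Sox17, a transcription factor of endoderm, where the others had 279 to 929 CPM. Values without this library are given where it changes the call or sign of a named gene or the camera call of a list. The series 1 passage 2 library still had 132 CPM of Col1a1, the main fibrillar collagen gene, against 0 to 5.44 CPM in the 8 that remain besides these.

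**Figure D1:**
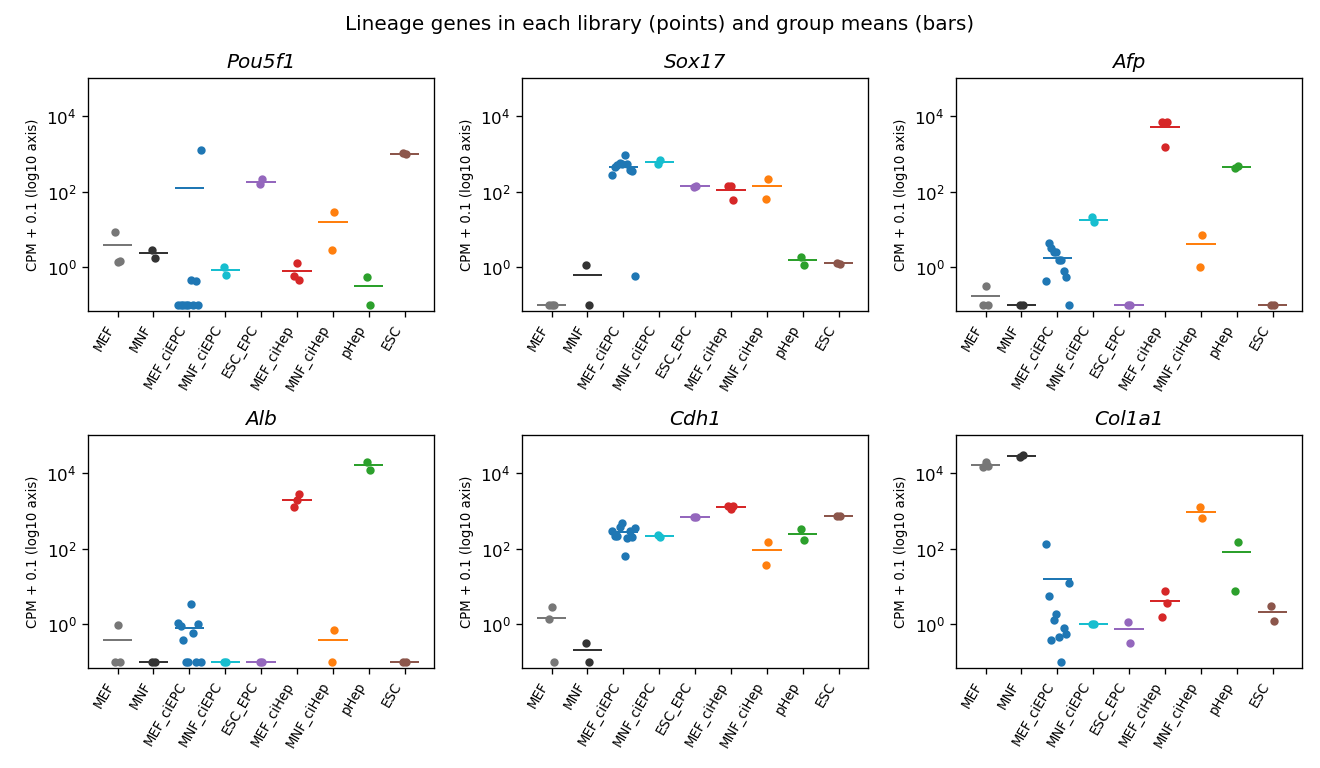
Expression of 6 lineage genes in each library, in CPM with 0.1 added, on a log10 axis, with the 28 libraries arranged by group as points and horizontal bars at the means over the libraries of each group. Sox17 lies between 279 and 929 CPM in 9 of the 10 MEF_ciEPC libraries, and Alb lies above 1000 CPM in the 3 MEF_ciHep libraries and in pHep but at 0 and 0.59 CPM in MNF_ciHep.

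To determine what the chemical treatment changed in embryonic fibroblasts, MEF_ciEPC (n = 2 series) was compared with MEF (n = 3). Sox17 (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354) rose to 424 ± 172 against 0 CPM, at least 1614-fold higher, adjusted p = 2.42e-07. The other largest rises were in Aqp8, a water channel gene (745 ± 194 against 0 CPM, at least 2836-fold), Nxf7, an RNA export factor gene (281 ± 76.8 against 0 CPM, at least 1070-fold) and the chloride channel gene Clic6 (219 ± 129.5 against 0 CPM, at least 834-fold). Joining them was the signalling ligand gene Ihh (219 ± 4.25 against 0 CPM, at least 833-fold). The endoderm regulators Foxa2 (108 ± 16.7 against 0 CPM, at least 411-fold), Hnf4a (34.1 ± 21.3 against 0 CPM, at least 129.6-fold) and Gata4 (1090 ± 111 against 5.22 ± 2.93 CPM) also rose. So did the epithelial adhesion genes Cdh1 (260.2 ± 14.4 against 1.36 ± 1.38 CPM) and Epcam (239.6 ± 29.96 against 1.26 ± 1.16 CPM). The largest falls included that of Acta2, a smooth muscle actin gene, to 0.19 ± 0.0214 against 6449 ± 2266 CPM, 30430-fold lower, adjusted p = 5.87e-07. The contractile genes Actg2 (0.0292 ± 0.0413 against 349.8 ± 124 CPM, 9194-fold, counting interval 1649 to 363200) and Tagln (1.57 ± 0.335 against 2740 ± 1015 CPM) and the collagen gene Col8a1 (0.154 ± 0.218 against 356 ± 74.2 CPM, 3128-fold, counting interval 1070 to 15180) fell as well. The caveolar gene Sdpr (0.0583 ± 0.0825 against 220.3 ± 131 CPM, 2741-fold, counting interval 758 to 22650) and the receptor gene Gpr176 (0.0292 ± 0.0413 against 97.2 ± 29.5 CPM, 2497-fold, counting interval 447 to 98740) did so too. Col1a1 (chromosome 11, 94936224 to 94953042) fell to 13.6 ± 15.2 against 16130 ± 2087 CPM, 1161-fold lower, adjusted p = 1.13e-05, and the surface marker Thy1 to 9.3 ± 2.12 against 601 ± 185 CPM. The liver genes Alb and Afp had 0.621 ± 0.442 and 1.56 ± 1.34 CPM and were not called.

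Of 16062 genes tested, 2819 were higher and 2540 lower in MEF_ciEPC (2744 and 2719 without the library labelled series 2 passage 22). With limma on log2(TPM + 1) the split was 3218 and 1896. Among the gene lists fixed beforehand, the fibroblast list had 30 of 32 lower and 1 higher (30 and 1, camera adjusted p = 1.2e-16, and 0.1 with an estimated correlation), with a median log2 fold change of −5.74. The epithelial list had 28 of 28 higher (28, camera adjusted p = 1.9e-20, and 0.073 with an estimated correlation), with a median of 7.14 (6.39 at the count floors). The extraembryonic endoderm list, with Lama1, a laminin gene of basement membrane (6882 ± 98 CPM), had 18 of 21 higher and 1 lower (18 and 1, camera adjusted p = 1.8e-09, and 0.1 with an estimated correlation). There were 15 of 18 higher and 1 lower in the endoderm transcription factor list (15 and 1) and 10 of 19 higher and 2 lower in the hepatocyte transcription factor list (10 and 2). In the cholangiocyte list 10 of 15 were higher and 1 lower (10 and 1) and in the lung and stomach list 6 of 11 were higher (6). With an estimated correlation adjusted p was 0.073 to 0.37. The pluripotency list had 20 of 22 higher (21, camera adjusted p = 0.00011, and 0.4 with an estimated correlation). Without that library it had 7 higher and 5 lower (camera adjusted p = 0.13). The log2 fold change of Pou5f1 went from 5.22 ± 1.45 to −4.97 and that of Nanog from 6.17 ± 1.42 to −2.01. The genes that fell included 30 of 36 lower and 1 higher in the Hox list (30 and 2) and 7 of 10 lower and 1 higher in the TGF-beta target list (7 and 1). In the macrophage list 7 of 9 were lower (8) and in the stellate cell list 6 of 9 were lower (6). In the p53 and Ink4 list 7 of 17 were lower and 1 higher (7 and 1), in the muscle list 7 of 14 were lower and 1 higher (8 and 1) and in the imprinted gene list 9 of 20 were lower and 2 higher (10 and 2). Adjusted p was 0.1 to 0.46 with an estimated correlation where camera gave a call. Members also changed elsewhere, with 6 of 10 higher and 1 lower in the Wnt target list (6 and 2) and 6 of 13 higher and 3 lower in the endothelium list (6 and 3). In the pancreas list 3 of 7 were higher and 1 lower (3 and 1) and in the neural list 4 of 9 were lower and 2 higher (4 and 2).

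The same question was asked of neonatal dermal fibroblasts with MNF_ciEPC and MNF (n = 2 each). Expression rose most in S100g (2486 ± 178 against 0 CPM, at least 7977-fold higher, adjusted p = 3.58e-08), Aqp8 (812 ± 194 against 0 CPM, at least 2604-fold) and Cldn6 (336 ± 28.1 against 0 CPM, at least 1079-fold). Rises were also large in Rhox5, a homeobox gene of extraembryonic endoderm (226 ± 4.12 against 0 CPM, at least 725-fold), and Plbd1 (196 ± 1.69 against 0 CPM, at least 628-fold). Sox17 (611 ± 89.8 against 0.518 ± 0.733 CPM), Foxa2 (116 ± 13.1 against 0.207 ± 0.293 CPM, 555-fold, counting interval 153 to 4587), Hnf4a (46.9 ± 16.7 against 0 CPM, at least 150.4-fold) and Gata4 (1145 ± 47.2 against 0.311 ± 0.44 CPM, 3667-fold, counting interval 1255 to 17790) rose too. So did Cdh1 (217 ± 20.5 against 0.104 ± 0.146 CPM, 2096-fold, counting interval 376 to 82810), Epcam (209.9 ± 9.88 against 0.208 ± 0.00077 CPM, 1012-fold, counting interval 279.9 to 8362) and the fetal liver gene Afp (17.8 ± 3.77 against 0 CPM, at least 57.2-fold). The largest falls were in the secreted growth factor gene Ptn (0 against 3835 ± 239 CPM, at least 15490-fold lower, adjusted p = 1.46e-06) and the matrix genes Col6a3 (0 against 1707 ± 496 CPM, at least 6895-fold) and Bgn (0.176 ± 0.249 against 7455 ± 16.8 CPM, 45160-fold, counting interval 12500 to 372900). Further falls were those of Col1a1 (0.906 ± 0.0354 against 27580 ± 1517 CPM), the surface gene Cd248 (0 against 613 ± 52.4 CPM, at least 2475-fold) and Acta2 (0.0776 ± 0.11 against 2068 ± 488 CPM, 25040-fold, counting interval 4494 to 989100). The Y-linked gene Ddx3y, with 36.5 ± 8.83 CPM in MNF, had no counts in MNF_ciEPC (at least 147-fold lower). Y-linked genes together had 154 and 106 CPM in MNF and 0.788 and 1.82 CPM in MNF_ciEPC, which the labels do not trace to these MNF.

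In all, 2949 genes were higher and 3508 lower in MNF_ciEPC. The fibroblast list had 31 of 32 lower (31, camera adjusted p = 2.1e-15, and 0.18 with an estimated correlation). The epithelial list had 26 of 28 higher (26, camera adjusted p = 4.5e-18, and 0.13 with an estimated correlation). The extraembryonic endoderm list had 19 of 21 higher and 1 lower (19 and 1, camera adjusted p = 7.8e-09, and 0.18 with an estimated correlation). The cell cycle list had 28 of 29 higher (28, camera adjusted p = 2.8e-08, and 0.61 with an estimated correlation). The interferon response list had 11 of 15 lower (12, camera adjusted p = 3e-05, and 0.42 with an estimated correlation). There were 15 of 18 higher and 1 lower in the endoderm transcription factor list (15 and 1) and 29 of 36 lower and 3 higher in the Hox list (29 and 3). In the cholesterol synthesis list 8 of 20 were higher (8), in the unfolded protein response list 6 of 13 were lower and 1 higher (6 and 1) and in the Wnt target list 7 of 10 were higher and 2 lower (7 and 2). An estimated correlation gave adjusted p = 0.18 to 0.65 where camera gave a call. The cholesterol genes included Insig1. There were also 4 of 6 lower in the sex chromosome list (4) and 1 of 5 higher and 1 lower in the germline list (1 and 1). In the bile acid list 2 of 11 were higher and 2 lower (2 and 2) and in the gluconeogenesis list 6 of 13 were higher and 2 lower (7 and 2). Between the 2 origins, 1669 genes were higher in both ciEPC comparisons against 518 if independent, and 1957 were lower in both against 555. Only 59 of the genes higher and 19 of those lower in MEF_ciEPC moved the opposite way in MNF_ciEPC.

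Whether the change depended on the origin of the fibroblasts was tested as the interaction, the change in MNF_ciEPC minus that in MEF_ciEPC, in log2 units ± SE. It was higher for 990 genes and lower for 1436 (1103 and 1452 without the library labelled series 2 passage 22). The counts were 531 and 731 without MNF replicate 1, 723 and 906 without MNF replicate 2, 645 and 789 without MNF_ciEPC replicate 1, and 674 and 708 without MNF_ciEPC replicate 2. Gata4 rose more from MNF (4.07 ± 1.2, adjusted p = 0.0287). Col1a1 fell more (−4.67 ± 1.49, adjusted p = 0.0408, and 0.0684 without that library). It was not called without series 1, which holds the passage 2 library (−2.43 ± 1.53, adjusted p = 0.337), nor without any single replicate of MEF, MNF or MNF_ciEPC (adjusted p = 0.0578 to 0.148). Genes without counts in a group have no finite difference, and their adjusted p alone is given. Among them, Ddx3y had a negative difference (adjusted p = 0.016), which need not come from treatment. By fitted value, the largest positive differences were in Igf2os (6.62 ± 1.09), Pitx1 (6.36 ± 0.9) and Erdr1 (5.76 ± 1). With them were 3 genes without counts in MNF, Tpm3-rs7 (adjusted p = 0.0125), Pcna-ps2 (0.00112) and the adhesion gene Igsf11 (0.0144). The largest negative ones were in the prolactin family gene Prl2c3 (−12.25 ± 3.5) and 5 genes without counts in MNF_ciEPC. These were the related Prl2c2 (adjusted p = 0.0406), Col6a3 (0.0155), the Y-linked gene Eif2s3y (0.00292), the interferon-induced gene Slfn5 (0.000534) and Apod (0.000789). The cell cycle list, with the DNA replication genes Mcm2 and Mcm3, had 26 of 29 higher (28, camera adjusted p = 7.2e-14, and 0.91 with an estimated correlation). There were 11 of 15 lower in the interferon response list (12) and 10 of 32 lower in the fibroblast list (13). In the hepatoblast list 6 of 18 were higher and 1 lower (7 and 1), in the unfolded protein response list 5 of 13 were lower (6) and in the sex chromosome list 3 of 6 were lower (4). Under an estimated correlation adjusted p was 0.91 where camera gave a call. The unfolded protein response list had a camera adjusted p of 0.065, and 0.038 without that library. Mean log2 CPM over the fibroblast list was 5.26 in the series 1 passage 2 library, 1.67 to 2.85 in the other MEF_ciEPC libraries and 2.03 and 1.83 in MNF_ciEPC, and no fit left out that library alone. For the cell cycle list it was 4.74 and 4.91 in MNF, 6.66 to 7.09 in MEF, 7.11 and 7.14 in MNF_ciEPC and 6.35 to 7.8 in MEF_ciEPC. For the interferon response list it was 4.65 and 4.61 in MNF, 1.74 to 2.49 in MEF, 1.79 and 1.3 in MNF_ciEPC and 0.95 to 2.37 in MEF_ciEPC. For both lists the origins thus lay apart in the fibroblasts and overlapped in the ciEPCs.

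ESC_EPC was compared with ESC (n = 2 each). The labels do not say that ESC_EPC came from these ESC, and Y-linked genes together had 0.842 and 0.225 CPM in ESC_EPC against 119 and 145 CPM in ESC. The strongest rises were those of the carbonic anhydrase gene Car4 (447 ± 38.4 against 0 CPM, at least 1298-fold higher, adjusted p = 0.000278) and the mesendoderm and early epiblast genes Lhx1 (277 ± 37.8 against 0 CPM, at least 806-fold) and Fgf5 (144 ± 5.02 against 0 CPM, at least 420.1-fold). Further rises were those of Dgkk (144 ± 0.464 against 0 CPM, at least 419.8-fold), the retinoic acid hydroxylase gene Cyp26a1 (131 ± 12.8 against 0 CPM, at least 380.3-fold) and Amot (3147 ± 104 against 0.482 ± 0.682 CPM). Sox17 (137 ± 7.44 against 1.16 ± 0.0539 CPM), Foxa2 (61.6 ± 8.75 against 0.761 ± 0.622 CPM) and Hnf4a (5.58 ± 0.0746 against 0.441 ± 0.0578 CPM) rose, as did Gata4 (68.4 ± 15.7 against 2.12 ± 0.959 CPM) and Epcam (241 ± 0.743 against 77.9 ± 16.6 CPM). Expression fell most in Trpm1 (0 against 86 ± 16.5 CPM, at least 267-fold lower, adjusted p = 0.000517) and the pluripotency-linked genes Tcl1 (0 against 83.9 ± 9.33 CPM, at least 261-fold) and Platr13 (0 against 39.7 ± 17.1 CPM, at least 123-fold). Others were the oocyte and stem cell gene Khdc3 (0 against 63.1 ± 12.7 CPM, at least 196-fold), Ddx3y (0 against 57 ± 12.1 CPM, at least 177-fold) and Bhmt (0 against 35.6 ± 6.27 CPM, at least 111-fold). Nanog fell to 21.9 ± 8.34 against 724 ± 175 CPM. Pou5f1 had 182 ± 38.7 against 1011 ± 14.6 CPM (log2 fold change −2.48 ± 1.31, adjusted p = 0.139), and was called lower at an adjusted p of 0.00188 when the library labelled series 2 passage 22 was left out of the fit. In ESC_EPC, 2978 genes were higher and 2355 lower. The pluripotency list had 16 of 22 lower and 1 higher (17 and 1, camera adjusted p = 2.5e-06, and 0.48 with an estimated correlation). The mesendoderm and Nodal list, with T and Cxcr4, had 9 of 15 higher and 1 lower (9 and 1, camera adjusted p = 0.00023, and 0.48 with an estimated correlation). There were 22 of 28 higher and 1 lower in the epithelial list (23 and 1) and 13 of 18 higher and 3 lower in the endoderm transcription factor list (13 and 3). In the extraembryonic endoderm list 10 of 21 were higher and 3 lower (12 and 3) and in the cell cycle list 28 of 29 were lower (28). In the p53 and Ink4 list 10 of 17 were higher (10) and in the imprinted gene list 12 of 20 were higher and 1 lower (13 and 1). Adjusted p was 0.48 to 0.85 with an estimated correlation. The imprinted genes included Nnat and Peg3. There were also 4 of 6 lower in the sex chromosome list (4), 4 of 9 higher and 1 lower in the neural list (4 and 2) and 5 of 22 lower and 3 higher in the fatty acid oxidation list (5 and 3). An estimated correlation gave adjusted p = 0.48 where camera gave a call.

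How closely the chemically induced progenitors matched those made from stem cells was examined by comparing MEF_ciEPC (n = 2 series) with ESC_EPC (n = 2). Rises were largest in Aqp8 (745 ± 194 against 0 CPM, at least 2315-fold higher, adjusted p = 1.75e-06), the proteoglycan gene Srgn (648 ± 16.3 against 0.111 ± 0.156 CPM, 6071-fold, counting interval 1089 to 239800) and the thrombomodulin gene Thbd (95.6 ± 9.57 against 0 CPM, at least 297-fold). Others were Rarres1 (50.1 ± 7.59 against 0 CPM, at least 156-fold), Car8 (40.8 ± 6.86 against 0 CPM, at least 127-fold) and Nostrin (36.7 ± 3.17 against 0 CPM, at least 114-fold). Sox17 was 3.1-fold higher and Gata4 15.9-fold higher, while Cdh1 was 2.63-fold lower. The strongest falls were those of the Nodal antagonist gene Cer1 (0 against 80.03 ± 15.9 CPM, at least 717-fold lower, adjusted p = 4.84e-05) and the growth factor genes Fgf5 (0.0292 ± 0.0413 against 144 ± 5.02 CPM, 3881-fold, counting interval 695 to 153400) and Fgf8 (0.0292 ± 0.0413 against 81.7 ± 20.04 CPM, 2186-fold, counting interval 391 to 86440). Joining them were Otog (0.0513 ± 0.0726 against 116 ± 11 CPM, 3120-fold, counting interval 559 to 123300), Irs4 (0.226 ± 0.175 against 340.3 ± 11.8 CPM) and Lhx1 (0.314 ± 0.299 against 277 ± 37.8 CPM). Pou5f1 had 128 ± 181 against 182 ± 38.7 CPM (log2 fold change −0.51 ± 1.25, adjusted p = 0.77) and Nanog 90.6 ± 128 against 21.9 ± 8.34 CPM (log2 fold change 2.04 ± 1.16, adjusted p = 0.169). Without the library labelled series 2 passage 22 both were called lower, with log2 fold changes of −10.71 and −6.15. Here 2700 genes were higher and 2393 lower in MEF_ciEPC (2857 and 2767 without that library). The mesendoderm and Nodal list had 11 of 15 lower and 1 higher (11 and 1, camera adjusted p = 4.7e-09, and 0.041 with an estimated correlation). The extraembryonic endoderm list had 20 of 21 higher and 1 lower (20 and 1, camera adjusted p = 5.9e-12, and 0.19 with an estimated correlation). There were 14 of 17 lower in the p53 and Ink4 list (14) and 7 of 11 higher and 1 lower in the lung and stomach list (7 and 1). In the cell cycle list 11 of 29 were higher (11) and in the Hox list 13 of 36 were higher and 3 lower (13 and 3). In the neural list 5 of 9 were lower and 2 higher (5 and 2) and in the imprinted gene list 9 of 20 were lower and 7 higher (9 and 7). With an estimated correlation adjusted p was 0.22 to 0.95 where camera gave a call. The p53 targets included Mdm2 and Bbc3. The pluripotency list had 8 of 22 higher and 2 lower (8 and 2), and 1 higher and 9 lower without that library. Camera adjusted p went from 0.59 to 0.033 for this list and from 0.093 to 0.033 for the neural list without it.

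MEF_ciEPC was also set against ESC (n = 2). The largest rises were in Robo2 (91.4 ± 1.89 against 0 CPM, at least 266-fold higher, adjusted p = 5.38e-07), Nfatc1 (87.5 ± 27.3 against 0 CPM, at least 254-fold) and the basement membrane collagen gene Col4a1 (9219 ± 216 against 4.05 ± 1.64 CPM). Joining them were Col4a2 (6752 ± 336 against 2.09 ± 0.686 CPM), the growth factor gene Igf2 (731 ± 514 against 0.161 ± 0.227 CPM, 3624-fold, counting interval 1003 to 29920) and Frmpd1 (67.5 ± 4.09 against 0 CPM, at least 196-fold). Falls were largest in Adarb2 (1.19 ± 1.51 against 79.8 ± 2.13 CPM, 72.8-fold lower, adjusted p = 0.000241), Khdc3 (1.06 ± 1.41 against 63.1 ± 12.7 CPM) and Zfp986 (0.879 ± 0.5 against 39.8 ± 12.1 CPM). The others were Trh (3.63 ± 3.57 against 149 ± 27.6 CPM), Arc (2.58 ± 1.58 against 92.6 ± 46.6 CPM) and Ttn (4.49 ± 5.12 against 129 ± 12.8 CPM). Nanog was 8.05-fold lower, a log2 fold change of −3.01 ± 1.14, and Pou5f1 had 128 ± 181 against 1011 ± 14.6 CPM (log2 fold change −2.99 ± 1.33, adjusted p = 0.0829). Without that library the log2 fold changes were −11.2 and −13.18. In number, 2990 genes were higher and 1964 lower (3314 and 2612 without that library). Without series 1 they were 2343 and 1158, and without ESC replicate 2 they were 2242 and 1272. The extraembryonic endoderm list had 21 of 21 higher (21, camera adjusted p = 2.8e-17, and 0.062 with an estimated correlation). The pluripotency list had 11 of 22 lower (13, camera adjusted p = 5.6e-06, and 0.56 with an estimated correlation), and 19 of 22 lower and 1 higher without that library. There were 11 of 18 higher in the endoderm transcription factor list (11) and 11 of 15 higher and 3 lower in the cholangiocyte list (11 and 3). In the epithelial list 18 of 28 were higher and 3 lower (19 and 3), in the cell cycle list 11 of 29 were lower (11) and in the fibroblast list 13 of 32 were higher and 2 lower (13 and 2). Adjusted p was 0.062 to 0.82 with an estimated correlation.

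Whether MEF_ciEPC changed with time in culture was tested as a trend on log2 passage over the 10 libraries, with the series as a term. No gene of 9138 was called by edgeR, and 1004 had an unadjusted p under 0.05. Without the library labelled series 2 passage 22 the numbers were 0 of 9767 and 1399. DESeq2 called 94 genes higher and 139 lower with passage, limma on log2(TPM + 1) called 0 and 1, and edgeR without the low-count filter 10 and 8. That filter drops genes that switch on or off within the series. The epithelial list had 0 of 17 higher and 0 lower (0 and 5, camera adjusted p = 4.4e-06, and 0.56 with an estimated correlation), with a median of −0.2 log2 units per doubling of passage. Without that library the median was −0.07 and the camera adjusted p 0.035. The fatty acid oxidation (camera adjusted p = 0.035), cholesterol synthesis (0.035), immediate early (0.046), TGF-beta target (0.046) and imprinted gene (0.046) lists had a downward camera call and no called member. Without that library the camera values were 0.041, 0.035, 0.42, 0.23 and 0.11. Their values were adjusted p = 0.56, 0.75, 0.7, 0.56 and 0.62 with an estimated correlation.

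**Figure D2:**
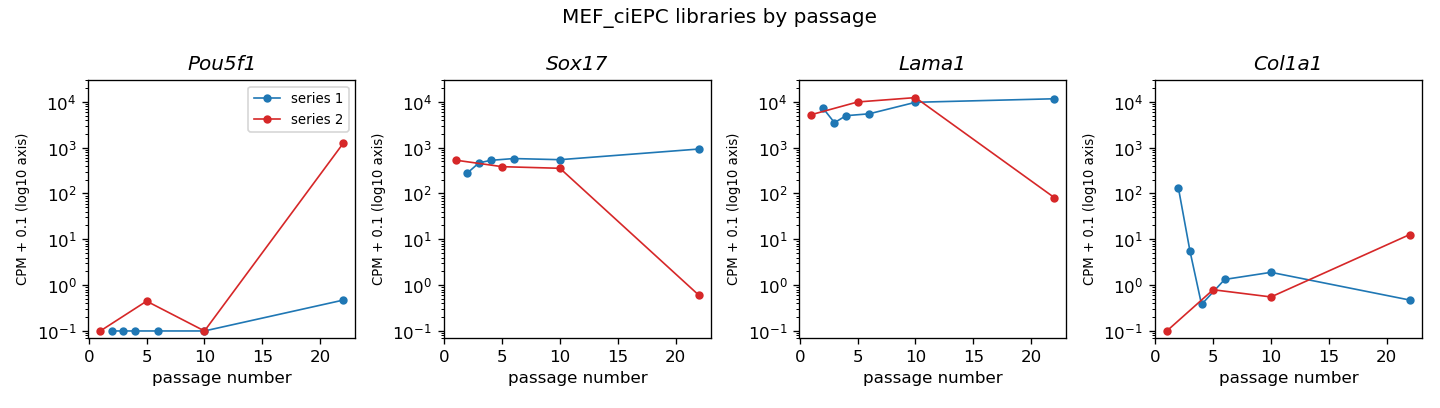
Expression of Pou5f1, Sox17, Lama1 and Col1a1 in the 10 MEF_ciEPC libraries against passage number, in CPM with 0.1 added on a log10 axis, 1 point per library joined within each series. Sox17 falls to 0.503 CPM and Pou5f1 rises to 1250 CPM only in the passage 22 library of series 2, and Col1a1 is highest, at 132 CPM, in the passage 2 library of series 1.

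To follow the step from progenitor to hepatocyte-like cell, MEF_ciHep (n = 3) was compared with MEF_ciEPC (n = 2 series). Afp (ENSMUSG00000054932, chromosome 5, 90490737 to 90508907) rose to 4960 ± 2973 against 1.56 ± 1.34 CPM, 2891-fold higher, adjusted p = 2.16e-06. Alb, the gene of serum albumin (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602), rose to 1904 ± 709 against 0.621 ± 0.442 CPM, 2702-fold higher, adjusted p = 7.67e-07. Ttr, the gene of the carrier protein transthyretin, rose to 452 ± 103 against 0.855 ± 0.193 CPM, 498-fold higher, adjusted p = 1.91e-06. Hnf4a was 4.66-fold higher, Cdh1 4.67-fold higher, and the cytochrome gene Cyp3a11 had 17.8 ± 20.3 against 0.0583 ± 0.0825 CPM, 337-fold, counting interval 92.5 to 2798. Expression rose most in the placental hormone genes Prl3d1 (504 ± 462 against 0 CPM, at least 4516-fold), Prl7a1 (241 ± 269 against 0 CPM, at least 2158-fold) and Prl3d2 (223 ± 207 against 0 CPM, at least 1995-fold). The others were Psg29 (402 ± 404 against 0.0292 ± 0.0413 CPM, 10620-fold, counting interval 1904 to 419400), the iron carrier gene Trf (8964 ± 5254 against 1.58 ± 1.65 CPM) and Pfpl (97.8 ± 119.8 against 0 CPM, at least 876-fold). The largest falls were in Dpysl4 (0.0563 ± 0.0976 against 36.3 ± 9.85 CPM, 419-fold, counting interval 75.1 to 16570) and the receptor genes Ephb1 (0.172 ± 0.174 against 39.99 ± 9.51 CPM, 209-fold, counting interval 57.7 to 1728) and Grik3 (1.84 ± 1.13 against 84 ± 15.8 CPM). Further falls were those of the threonine dehydrogenase gene Tdh (0.63 ± 0.7 against 109 ± 26 CPM), Fbn1 (1.04 ± 0.763 against 119 ± 67.2 CPM) and the Wnt feedback gene Axin2 (1.41 ± 0.404 against 98.5 ± 9.56 CPM). Sox17 was 3.87-fold lower and Gata4 5.32-fold lower.

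In MEF_ciHep, 2864 genes were higher and 2385 lower (3003 and 2218 without the library labelled series 2 passage 22). With limma on log2(TPM + 1) the split was 2051 higher and 3150 lower. The plasma protein list had 28 of 31 higher (29, camera adjusted p = 5.1e-19, and 0.018 with an estimated correlation), with a median log2 fold change of 6.93 (6.9 at the count floors). The drug metabolism list had 18 of 23 higher and 1 lower (20 and 1, camera adjusted p = 1.8e-08, and 0.012 with an estimated correlation). The interferon response list had 15 of 15 higher (15, camera adjusted p = 1.9e-12, and 0.091 with an estimated correlation). There were 18 of 28 higher in the epithelial list (18) and 10 of 19 higher in the hepatocyte transcription factor list (10). In the urea cycle list 7 of 20 were higher (6) and in the fatty acid oxidation list 11 of 22 were higher (12). In the lung and stomach list 8 of 11 were higher and 0 lower (8 and 1), in the intestine list 10 of 15 were higher and 3 lower (10 and 3) and in the muscle list 6 of 14 were higher (6). An estimated correlation gave adjusted p = 0.06 to 0.47. The lung and stomach genes included Cldn18, Muc5ac and Gkn2. In the other direction there were 29 of 29 lower in the cell cycle list (29) and 8 of 10 lower in the Wnt target list (9). In the extraembryonic endoderm list 14 of 21 were lower and 2 higher (14 and 3) and in the Hox list 15 of 36 were lower (15). Under an estimated correlation adjusted p was 0.06 to 0.49. The pluripotency list had 14 of 22 lower (14, camera adjusted p = 0.013, and 0.57 with an estimated correlation), and 5 higher and 3 lower without that library (camera adjusted p = 0.95).

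In cells of neonatal origin MNF_ciHep was compared with MNF_ciEPC (n = 2 each). Alb, with 0 counts in MNF_ciEPC, had 0.288 ± 0.407 CPM and was not called. Afp was 5.49-fold lower and Hnf4a 6.6-fold lower, while Ttr had 6.72 ± 3.81 against 1.11 ± 0.917 CPM. Col1a1 rose to 935 ± 449 against 0.906 ± 0.0354 CPM, 1003-fold higher, adjusted p = 6.19e-05, and Thy1 to 237 ± 197 against 17.5 ± 13 CPM. The strongest rises were those of Lcn2 (285 ± 142 against 0 CPM, at least 1150-fold) and the matrix genes Efemp1 (265 ± 158 against 0 CPM, at least 1070-fold) and Olfml3 (201 ± 182 against 0 CPM, at least 812-fold). Further rises were those of Ldoc1 (156 ± 71.4 against 0 CPM, at least 629-fold) and Crabp2 (145 ± 118 against 0 CPM, at least 585-fold). Expression fell most in Tpm3-rs7 (0 against 164 ± 2.38 CPM, at least 276-fold), Sox14 (0.288 ± 0.407 against 51.5 ± 6.38 CPM, 258-fold, counting interval 46.1 to 10200) and Mogat1 (0.456 ± 0.644 against 73.5 ± 24 CPM, 125-fold, counting interval 42.7 to 608). Others were Aifm3 (2.48 ± 1.37 against 272 ± 27.7 CPM), Scml4 (0.44 ± 0.192 against 37.2 ± 17.2 CPM, 91.6-fold, counting interval 25.2 to 758) and Fam105a (6.43 ± 4.22 against 394 ± 16.8 CPM). The X-linked silencing RNA Xist was 13.8-fold lower, and Ddx3y rose from 0 to 24.5 ± 4.49 CPM.

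There were 3135 genes higher and 1739 lower in MNF_ciHep, and 2597 and 2203 with limma on log2(TPM + 1). The fibroblast list had 30 of 32 higher (30, camera adjusted p = 6.7e-13, and 0.38 with an estimated correlation). The plasma protein list had 15 of 31 higher (18, camera adjusted p = 0.00021, and 0.38 with an estimated correlation). There were 24 of 36 higher in the Hox list (25) and 13 of 15 higher in the interferon response list (13). In the immediate early list 14 of 16 were higher (14), in the stellate cell list 7 of 9 were higher (7) and in the drug metabolism list 9 of 23 were higher (9). Adjusted p was 0.38 with an estimated correlation. The immediate early genes included Ier3 and Dusp1. There were also 13 of 28 lower and 2 higher in the epithelial list (13 and 2) and 11 of 29 lower in the cell cycle list (12). In the endothelium list 6 of 13 were higher (8) and in the neural list 6 of 9 were higher (6). In the p53 and Ink4 list 7 of 17 were higher (7) and in the sex chromosome list 4 of 6 were higher and 1 lower (4 and 1). An estimated correlation gave adjusted p = 0.56 to 0.76 where camera gave a call. The ciHep steps of the 2 origins shared 1041 genes higher (559 if independent) and 526 lower (258). The opposite way in MNF_ciHep went 222 of those higher and 381 of those lower in MEF_ciHep.

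The dependence of this step on origin was tested as the change into MNF_ciHep minus the change into MEF_ciHep, in log2 units ± SE. It was higher for 2833 genes and lower for 1923 (2687 and 1880 without the library labelled series 2 passage 22). By fitted value, the largest positive differences were in genes without counts in MEF_ciHep or MNF_ciEPC. They were the mast cell protease gene Mcpt1 (adjusted p = 0.0017), the mesenchymal transcription factor gene Twist2 (0.000256), Col6a3 (0.000656), the cornified envelope gene Sprr1b (0.00454), the matrix protease gene Mmp3 (0.00104) and Cldn11 (0.000484). The largest negative ones were in Afp (−13.96 ± 1.24, adjusted p = 7.91e-06), and 5 genes without counts in MNF_ciHep. These were Tpm3-rs7 (adjusted p = 0.00148), the stomach protease gene Ctse (0.000584), Akr1c19 (0.000301), Gsdma2 (0.000429) and the cytochrome gene Cyp2c65 (0.00225). The difference was positive for Col1a1 (11.56 ± 1.62, adjusted p = 8.99e-05) and Thy1 (9.26 ± 1.17) and negative for Ttr (−6.25 ± 1.25), Cdh1 (−3.47 ± 0.71) and Hnf4a (−4.94 ± 0.7). The fibroblast list had 30 of 32 higher (30, camera adjusted p = 1.8e-14, and 0.12 with an estimated correlation). The epithelial list had 22 of 28 lower (23, camera adjusted p = 3e-11, and 0.12 with an estimated correlation). There were 24 of 36 higher in the Hox list (27) and 20 of 29 higher in the cell cycle list (23). In the Wnt target list 8 of 10 were higher (8) and in the immediate early list 10 of 16 were higher (11). In the stellate cell list 8 of 9 were higher (8), in the TGF-beta target list 5 of 10 were higher (5) and in the neural list 5 of 9 were higher (5). With an estimated correlation adjusted p was 0.11 to 0.59. The TGF-beta target list had a camera adjusted p of 0.035, and 0.054 without that library. In the other direction there were 11 of 22 lower and 2 higher in the fatty acid oxidation list (11 and 2), 6 of 31 lower and 1 higher in the plasma protein list (6 and 1) and 5 of 11 lower and 1 higher in the lung and stomach list (5 and 1). Adjusted p was 0.11 to 0.16 with an estimated correlation. The sex chromosome list had 3 of 6 higher and 1 lower (4 and 1).

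Each kind of ciHep was then compared with primary hepatocytes. In MEF_ciHep (n = 3) relative to pHep (n = 2), Alb had 1904 ± 709 against 15310 ± 5174 CPM, 8.04-fold lower, adjusted p = 0.000246. Ttr had 452 ± 103 against 1268 ± 955 CPM, 2.81-fold lower, adjusted p = 0.0157, and was not called without pHep replicate 1 (log2 fold change −0.38 ± 0.32, adjusted p = 0.448, against −2.15 ± 0.31 without replicate 2). Hnf4a had 160 ± 32.4 against 542 ± 114 CPM, and Afp had 4960 ± 2973 against 433 ± 39.9 CPM, 11.4-fold higher, adjusted p = 0.00125. Cyp3a11 had 17.8 ± 20.3 against 21.5 ± 14.5 CPM (log2 fold change −0.23 ± 0.9, adjusted p = 0.881). Rises were largest in the mucosal gene Dmbt1 (1589 ± 581 against 0 CPM, at least 2306-fold) and the prolactin family genes Prl3d1 (504 ± 462 against 0 CPM, at least 732-fold) and Prl7a1 (241 ± 269 against 0 CPM, at least 349.7-fold). Others were Prl3d3 (215 ± 191 against 0 CPM, at least 313-fold), Tcf23 (186 ± 66.6 against 0 CPM, at least 269-fold) and Degs2 (180.2 ± 53.3 against 0 CPM, at least 262-fold). The strongest falls were those of the major urinary protein genes Mup7 (0 against 1652 ± 2330 CPM, at least 6035-fold), Mup3 (0.113 ± 0.195 against 618 ± 573 CPM, 3605-fold, counting interval 997 to 29780) and Mup2 (0 against 54.6 ± 19.6 CPM, at least 199.7-fold). Joining them were Mup16 (0 against 54.1 ± 72.9 CPM, at least 198-fold), the lectin gene Mbl2 (0.0563 ± 0.0976 against 377 ± 54.8 CPM, 4173-fold, counting interval 748 to 164900) and Lmcd1 (0 against 83.5 ± 42 CPM, at least 305-fold). Mup7 had 3490 and 4.34 CPM and Mup16 112 and 2.71 CPM in pHep replicates 1 and 2, so both falls rest on replicate 1. These replicates also had 68.1 and 0 CPM of the Y-linked gene Ddx3y. Epcam was 199-fold higher, Cdh1 5.13-fold higher, Sox17 78.4-fold higher and Gata4 14.7-fold higher. In all, 2430 genes were higher and 1738 lower. The bile acid list had 8 of 11 lower (8, camera adjusted p = 2.4e-06, and 0.022 with an estimated correlation). The gluconeogenesis list had 8 of 13 lower (8, camera adjusted p = 0.00019, and 0.021 with an estimated correlation). The lung and stomach list had 9 of 11 higher (10, camera adjusted p = 7.8e-08, and 0.021 with an estimated correlation). There were 26 of 31 lower in the plasma protein list (27) and 12 of 20 lower and 1 higher in the urea cycle list (13 and 1). In the hepatocyte transcription factor list 10 of 19 were lower (10), in the drug metabolism list 9 of 23 were lower and 1 higher (9 and 1) and in the macrophage list 8 of 9 were lower and 1 higher (8 and 1). An estimated correlation gave adjusted p = 0.062 to 0.36. The pHep replicates 1 and 2 lay apart in lists of other cells, with mean log2 CPM of 2.05 and 4.29 for macrophage, 0.84 and 3 for stellate cell and 2.38 and 4.66 for fibroblast. In the other direction there were 22 of 28 higher in the epithelial list (22) and 16 of 21 higher and 2 lower in the extraembryonic endoderm list (16 and 2). In the imprinted gene list 14 of 20 were higher (15) and in the cholesterol synthesis list 9 of 20 were higher and 1 lower (9 and 1). In the interferon response list 6 of 15 were higher (7) and in the intestine list 9 of 15 were higher and 1 lower (9 and 1). Under an estimated correlation adjusted p was 0.066 to 0.52.

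In MNF_ciHep relative to pHep (n = 2 each), Alb was the largest fall, with 0.288 ± 0.407 against 15310 ± 5174 CPM, 78830-fold lower, counting interval 14150 to 3114000, adjusted p = 5.55e-07. Mup7 (0 against 1652 ± 2330 CPM, at least 2770-fold) and Tm4sf4 (0 against 981 ± 509 CPM, at least 1646-fold) were also among the largest falls, that of Mup7 resting on the 3490 CPM of pHep replicate 1. So were the antitrypsin genes Serpina1c (0 against 934 ± 1190 CPM, at least 1566-fold) and Serpina1b (0 against 678 ± 680.4 CPM, at least 1136-fold) and Mup3 (0 against 618 ± 573 CPM, at least 1035-fold). In pHep replicates 1 and 2, Serpina1c had 1880 and 98.2 CPM, Serpina1b 1230 and 209 CPM and Mup3 1080 and 226 CPM. Hnf4a was 76.4-fold lower, Afp 133-fold lower, Ttr 175-fold lower and Cyp3a11 at least 36-fold lower. The largest rises were in the water channel gene Aqp5 (192 ± 11.8 against 0 CPM, at least 278-fold), Mcpt1 (164 ± 37.8 against 0 CPM, at least 238-fold) and Ldoc1 (156 ± 71.4 against 0 CPM, at least 226-fold). Joining them were the epidermal gene Sprr2b (99.9 ± 64.8 against 0 CPM, at least 145-fold), Brinp3 (94.2 ± 48.5 against 0 CPM, at least 137-fold) and the Nodal co-receptor gene Tdgf1 (95.7 ± 73.8 against 0 CPM, at least 139-fold). Epcam was 74.2-fold higher, Sox17 94.6-fold higher, Gata4 28.6-fold higher, Col1a1 12.5-fold higher and Thy1 406-fold higher, counting interval 139 to 1973. In number, 2950 genes were higher and 2153 lower. The plasma protein list had 29 of 31 lower (30, camera adjusted p = 5.5e-22, and 0.007 with an estimated correlation). The drug metabolism list had 16 of 23 lower and 2 higher (18 and 2, camera adjusted p = 1.2e-07, and 0.007 with an estimated correlation). The hepatocyte transcription factor list had 16 of 19 lower and 1 higher (16 and 1, camera adjusted p = 1.2e-07, and 0.048 with an estimated correlation). The urea cycle list had 14 of 20 lower and 1 higher (14 and 1, camera adjusted p = 1.2e-07, and 0.032 with an estimated correlation). The gluconeogenesis list had 11 of 13 lower (11, camera adjusted p = 9.9e-07, and 0.0065 with an estimated correlation). The bile acid list had 8 of 11 lower and 1 higher (9 and 1, camera adjusted p = 6.9e-06, and 0.025 with an estimated correlation). There were 14 of 22 lower and 1 higher in the fatty acid oxidation list (14 and 1) and 30 of 36 higher in the Hox list (31). In the imprinted gene list 17 of 20 were higher (17) and in the fibroblast list 24 of 32 were higher and 2 lower (24 and 2). In the extraembryonic endoderm list 18 of 21 were higher and 1 lower (18 and 1) and in the Wnt target list 8 of 10 were higher and 1 lower (8 and 1). Adjusted p was 0.06 to 0.38 with an estimated correlation.

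Both ciHep groups were finally compared with the fibroblasts they came from. In MEF_ciHep (n = 3), 3670 genes were higher and 3106 lower than in MEF (n = 3). Expression rose most in the apolipoprotein gene Apoa1 (9224 ± 4144 against 0 CPM, at least 35110-fold higher, adjusted p = 1.41e-06) and the stomach genes Gkn2 (7010 ± 4593 against 0 CPM, at least 26680-fold) and Gkn1 (6092 ± 4542 against 0 CPM, at least 23190-fold). The others were the gut lining genes Tff1 (3731 ± 1596 against 0 CPM, at least 14200-fold), Dmbt1 (1589 ± 581 against 0 CPM, at least 6047-fold) and Zg16 (1462 ± 1036 against 0 CPM, at least 5565-fold). Falls were largest in Tll1 (0 against 117 ± 59.4 CPM, at least 428-fold) and the matrix genes Tnc (0.733 ± 1.27 against 4796 ± 769.9 CPM) and Aspn (0 against 106 ± 23.1 CPM, at least 387-fold). The others were Col1a1 (4.04 ± 2.98 against 16130 ± 2087 CPM), Fibin (0 against 108 ± 12.2 CPM, at least 394-fold) and Twist2 (0 against 106 ± 11.9 CPM, at least 388-fold). The plasma protein list had 29 of 31 higher (29, camera adjusted p = 9.2e-16, and 0.018 with an estimated correlation). The epithelial list had 28 of 28 higher (28, camera adjusted p = 5.4e-19, and 0.026 with an estimated correlation). The drug metabolism (adjusted p = 0.018), gluconeogenesis (0.018), cholangiocyte (0.018), intestine (0.018), lung and stomach (0.018) and Hox (0.044) lists also kept their camera calls with an estimated correlation. They had 18, 11, 10, 11 and 9 members higher in that order and 34 Hox genes lower. There were 15 of 15 higher in the interferon response list (15) and 27 of 29 lower in the cell cycle list (27). In the hepatocyte transcription factor list 15 of 19 were higher and 2 lower (15 and 2) and in the hepatoblast list 6 of 18 were higher and 4 lower (6 and 4). An estimated correlation gave adjusted p = 0.08 to 0.32 where camera gave a call.

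In MNF_ciHep, 2597 genes were higher and 1857 lower than in MNF (n = 2 each). The strongest rises were those of S100g (579 ± 273 against 0 CPM, at least 1859-fold higher, adjusted p = 6.92e-07), Aqp8 (408 ± 257 against 0 CPM, at least 1308-fold) and the chitinase-like gene Chil1 (184 ± 165 against 0 CPM, at least 590.4-fold). Further rises were those of Ldoc1 (156 ± 71.4 against 0 CPM, at least 499.7-fold) and the surface gene Ly6d (122 ± 43.1 against 0 CPM, at least 391-fold). The largest falls were in Aspn (0 against 532 ± 34.5 CPM, at least 893-fold), Zcchc5 (0 against 64.4 ± 13.8 CPM, at least 108-fold) and Adgrd1 (0 against 61.9 ± 0.946 CPM, at least 104-fold). Further falls were those of Itgbl1 (0 against 36.6 ± 4.86 CPM, at least 61.3-fold), the tendon gene Tnmd (0.152 ± 0.215 against 229 ± 56.2 CPM, 1151-fold, counting interval 206 to 45500) and C1qtnf3 (0.743 ± 0.237 against 418 ± 13.7 CPM). The cholangiocyte list had 11 of 15 higher (13, camera adjusted p = 3.6e-06, and 0.027 with an estimated correlation). There were 27 of 28 higher in the epithelial list (28) and 15 of 18 higher in the endoderm transcription factor list (16). In the extraembryonic endoderm list 17 of 21 were higher and 1 lower (18 and 1) and in the plasma protein list 17 of 31 were higher (17). In the fibroblast list 19 of 32 were lower (21) and in the immediate early list 13 of 16 were higher (13). In the cell cycle list 18 of 29 were higher (19), in the Wnt target list 8 of 10 were higher and 1 lower (8 and 1) and in the hepatoblast list 11 of 18 were higher and 2 lower (11 and 2). With an estimated correlation adjusted p was 0.08 to 0.59. Against their fibroblasts, the ciHeps of both origins shared 1285 genes higher (593 if independent) and 864 lower (359). Of the MEF_ciHep changes, 179 of those higher and 388 of those lower moved the opposite way in MNF_ciHep.

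Finally, each library was placed between fibroblast and hepatocyte with gene sets chosen on these same libraries. There were 687 genes called at least 8-fold higher in pHep than in each of MEF, MNF and ESC, and 532 called at least 8-fold higher in both MEF and MNF than in pHep and ESC. The share of the hepatocyte-high genes within 4-fold of the pHep level was 38.2 ± 1.6% in MEF_ciHep (SD, n = 3) and 17.8 ± 2% in MNF_ciHep (n = 2). It was 12.3 ± 3% in MEF_ciEPC (n = 2), 12.9 ± 0.7% in MNF_ciEPC (n = 2) and 10.3 ± 0.6% in ESC_EPC (n = 2). The share of the fibroblast-high genes within 4-fold of the source fibroblasts was 46 ± 9.2% in MNF_ciHep, 15.2 ± 1% in MEF_ciHep, 16.1 ± 3.2% in MEF_ciEPC and 11.7 ± 0.1% in MNF_ciEPC. Without the library labelled series 2 passage 22, MEF_ciEPC had 13.6 ± 1.2% of the hepatocyte-high and 17.9 ± 0.6% of the fibroblast-high genes.

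**Figure D3:**
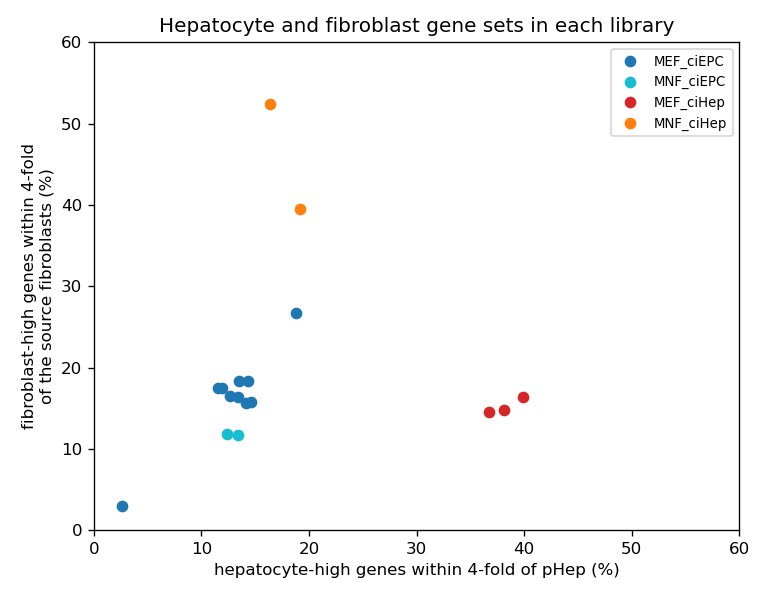
Percent of the 687 hepatocyte-high genes within 4-fold of pHep (x axis) against percent of the 532 fibroblast-high genes within 4-fold of the source fibroblasts (y axis), 1 point per library of the ciEPC and ciHep groups. The 3 MEF_ciHep points lie farthest to the right and the 2 MNF_ciHep points highest, and the library labelled series 2 passage 22 lies lowest on both axes at 2.6 and 3%.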

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

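Of the tests in this part, those of ciEPC-high genes, chromosome X and chromosome 1 in the library labelled MEF_ciEPC series 2 passage 22, and those of the 10th percentile and of Y-linked genes in MNF_ciHep, were chosen after the results were seen. The test of a common ratio to MNF and the splits of MEF_ciHep and MEF were fixed before.

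In the 10 MEF_ciEPC libraries, 39 measures were tested for a library far from the others by Dixon's 95% critical value, and 15 were past it. Chance puts about 1 in 20 such measures past it, and the lists share genes. For the library labelled MEF_ciEPC series 2 passage 22, the share of hepatocyte-high genes was 2.6% (11.5 to 18.8% in the others) and that of fibroblast-high genes 3% (15.6 to 26.7%). Its mean log2 CPM was low for the endoderm transcription factor list (1.16), the extraembryonic endoderm list (1.87), the hepatocyte transcription factor list (1.56), the cholangiocyte list (2.45) and the lung and stomach list (−0.49). It was high for the pluripotency list (7.56), the mesendoderm and Nodal list (3.13), the urea cycle list (1.93), the neural list (2.34) and the germline list (3.69).

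The first pattern is the likeness of this library to ESC. A mixture of ciEPCs with pluripotent cells is argued against by 451 genes at least 8-fold higher in MNF_ciEPC than in ESC. Their median ratio to MNF_ciEPC was 0.035 in this library, against 0.032 and 0.0285 in the ESC libraries. RNA of the same cells as the deposited ESC libraries is argued against by chromosome X, whose median log2 difference to ESC was 0.79 (bootstrap interval 0.72 to 0.89), where the ESC libraries differed by 0.13. Its Y-linked genes had 0 CPM, against 119 and 145 CPM in ESC. Series 2 cells that became pluripotent, and pluripotent cells of another origin under a wrong label, cannot be told apart. The chromosome 1 median of 0.09 against ESC could come from either. Y-linked genes had 165, 99.1 and 103 CPM at passages 1, 5 and 10 of series 2. They do not decide it, since series 1 also went from 63.9 CPM at passage 10 to 0.372 CPM at passage 22.

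The series 1 passage 2 library was high for the fibroblast list (5.26, others 1.67 to 2.85), the intestine list (3, others 0.79 to 1.82) and the TGF-beta target list (6.66, others 3.95 to 5.3) in mean log2 CPM.

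The tests of the difference between fibroblast sources gave, for the ciEPC step, 990 genes higher and 1436 lower from MNF, 26 cell cycle genes higher, 11 interferon response genes lower and 3 sex chromosome genes lower. Without MNF replicate 1 the genes were 531 and 731, and with an estimated correlation the cell cycle and interferon response lists had an adjusted p of 0.91. MNF had a mean log2 CPM of 4.74 and 4.91 over the cell cycle list, against 6.66 to 7.09 in MEF, where the ciEPCs of both origins overlapped. For the ciHep step they gave 2833 genes higher and 1923 lower, where MNF_ciHep and MNF_ciEPC also differed in implied length and in Y-linked RNA. Among the lists, 30 fibroblast genes, 24 Hox genes, 20 cell cycle genes, 10 immediate early genes, 8 stellate cell genes, 8 Wnt targets, 5 TGF-beta targets, 5 neural genes and 3 sex chromosome genes were higher. Lower were 22 epithelial and 11 fatty acid oxidation genes. With an estimated correlation, those of these lists with a camera call had an adjusted p of 0.11 to 0.59, and without the library labelled MEF_ciEPC series 2 passage 22 the TGF-beta target list had a camera adjusted p of 0.054.

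The second pattern is the level of fibroblast genes in MNF_ciHep. Over 199 fibroblast-high genes with at least 100 CPM in MNF, the median ratio to MNF was 0.224 and 0.143 in the 2 libraries. MNF with the profile of the MNF libraries as the source of all of that level are argued against, since they would bring all their abundant transcripts at 1 share. The 10th percentile of the ratio was 0.033 and 0.015. MNF changed by the treatment were not measured and stay open. Whether MNF make up part of it cannot be told apart from other sources. In the test of a common ratio, 43.2% (36.5 to 50.2%, Wilson 95% interval) and 39.2% (32.7 to 46.1%) of the genes lay within 2-fold of the median ratio. Both were under the 50% set as the bound, against a common ratio, but the first interval reaches it. A return to a fibroblast state of the very cells of the MNF_ciEPC libraries is argued against by the Y-linked genes, which summed to 96.5 and 98.5 CPM in MNF_ciHep and to 0.788 and 1.82 CPM in MNF_ciEPC. A fibroblast-like state of cells from another MNF_ciEPC culture was not tested.

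With 3 libraries each, MEF_ciHep and MEF allow 10 splits of the 6 libraries, too few for a share under 0.05. The real split called 5634 genes in a fit of these libraries alone, and the highest of the others called 0.

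Outside the series-wide table, the urinary protein gene Mup22, chosen after its values were seen, had 2373.5 CPM in pHep replicate 1, 31.7 CPM in pHep replicate 2 and at most 2.3 CPM in any other library.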

How the results depend on the processing

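The alternative without the library labelled MEF_ciEPC series 2 passage 22 was chosen after seeing the data, and the others were planned. Of 3638 values of named genes under the alternatives, 3450 kept their direction and their side of the threshold, 155 were no longer called, 17 became called and 16 changed sign. Of 483 list values, 331 kept their side of the threshold, and their direction was not compared. Of 161 list results, each of 1 list in 1 comparison, 119 lost their camera call with an estimated correlation. With fry 10 lost it and 14 gained a call. The cause of these changes was not tested except where the alternative removes libraries.

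Pou5f1 and Nanog changed sign with the library labelled MEF_ciEPC series 2 passage 22, in log2 units. In MEF_ciEPC against MEF, without it Pou5f1 was −4.97 and Nanog −2.01, and with only passages up to 5 they were −5.16 and −1.81. In MEF_ciEPC against ESC_EPC, Nanog was −6.15 without it, −5.95 up to passage 5 and −0.44 with limma on log2(TPM + 1).

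With the 10 MEF_ciEPC libraries as separate samples, the ciEPC interaction had 499 genes higher and 428 lower. It left 1454 lower in ESC_EPC against ESC, 1052 in MNF_ciHep against MNF_ciEPC and 1101 in MNF_ciHep against MNF. Without a fold minimum, 3082 were lower in MEF_ciEPC against ESC, 3780 in MEF_ciHep against MEF_ciEPC, 2807 in MNF_ciHep against MNF_ciEPC and 2667 in MEF_ciHep against pHep. With only the compared groups in the fit, 1722 were higher in MNF_ciHep against pHep. With a replicate block, MEF_ciEPC against MEF had 2679 higher and 2458 lower, and every comparison stayed within 1.5-fold of its counts. The trend called 94 higher and 139 lower with DESeq2 and 10 and 8 without the low-count filter. It called 1 higher in series 1 alone and 1 lower with limma on log2(TPM + 1), and 0 with edgeR.

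Leaving out each replicate, the ciEPC interaction ranged from 531 to 1024 higher and 708 to 1350 lower, with the lowest without MNF replicate 1 and MNF_ciEPC replicate 2. MEF_ciEPC against ESC ranged from 1158 lower without series 1 to 2245. The other counts stayed within 1.5-fold. Some log2 fold changes covered 0 over the same fits. In MEF_ciEPC against MEF these were Pou5f1 (−5.28 to 6.57), Nanog (−1.69 to 7.26) and Alb (−0.08 to 4.8). In MEF_ciEPC against ESC_EPC they were Pou5f1 (−11.04 to 0.56) and Nanog (−5.84 to 3.11). Cyp3a11 in MEF_ciHep against pHep ranged from −1.82 to 0.74, and Alb in MNF_ciHep against MNF_ciEPC from 0 to 4.52. The fibroblast-high share ranged from 11.7 to 11.8% in MNF_ciEPC and from 39.5 to 52.4% in MNF_ciHep.

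The median log2 fold change of the genes in each fit moved by over 0.1 with limma on log2(TPM + 1) in MEF_ciEPC against MEF (0.12 to 0.29), ESC_EPC against ESC (0 to 0.13) and MEF_ciEPC against ESC (0.04 to 0.16). It also moved there in MEF_ciHep against MEF_ciEPC (−0.07 to −0.29) and MNF_ciHep against pHep (0.11 to 0.24). With DESeq2 it moved in MEF_ciEPC against MEF (0.12 to 0), the ciEPC interaction (−0.18 to −0.06) and MNF_ciHep against pHep (0.11 to 0). The ciHep interaction moved from 0.18 to 0.07 with the low-count filter at 50 and with only the compared groups. MNF_ciHep against pHep moved from 0.11 to 0 with no filter and without MNF_ciHep replicate 1, and MEF_ciEPC against ESC from 0.04 to 0.16 without ESC replicate 2.

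With Spearman correlation, similarity was 0.814 for MEF_ciEPC and ESC_EPC, 0.724 for MNF_ciEPC and MNF and 0.825 for ESC_EPC and ESC. It was 0.803 for MEF_ciHep and pHep, 0.755 for MNF_ciHep and pHep, 0.694 for MEF_ciHep and MEF and 0.959 for the library labelled MEF_ciEPC series 2 passage 22 and ESC. On log2(TPM + 1) it was 0.723 for MNF_ciEPC and MNF, 0.823 for ESC_EPC and ESC and 0.746 for MNF_ciHep and pHep.

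With 4-fold instead of 8-fold to define the sets, hepatocyte-high shares were 18.6% in MEF_ciEPC, 20% in MNF_ciEPC, 45.8% in MEF_ciHep, 26.4% in MNF_ciHep and 17.7% in ESC_EPC. Fibroblast-high shares were 20.5% in MEF_ciEPC, 21.7% in MEF_ciHep and 15.6% in MNF_ciEPC. Within 2-fold instead of 4-fold, hepatocyte-high shares were 5.9, 7.1, 18.7, 7.8 and 4.1% in the same order. Fibroblast-high shares were then 7.6%, 6.3% and 5% in that order and 23.3% in MNF_ciHep. With TPM they were 14.6% in MNF_ciEPC, 19.9% in MNF_ciHep and 12.5% in ESC_EPC for hepatocyte-high and 13.4% in MNF_ciEPC for fibroblast-high genes. Depth limits genes of few counts, whose folds are bounds or wide intervals.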

Other observations

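Sex-linked genes differed between libraries of 1 group. Xist had 2.65 and 1640 CPM and Ddx3y 68.1 and 0 CPM in pHep replicates 1 and 2. In MEF_ciEPC series 1, Ddx3y had 32.7 CPM at passage 2 and 0.372 CPM at passage 22, and Xist had 403 and 3290 CPM. H19, a growth-restraining imprinted RNA chosen after its values were seen, had 1080, 3850, 1450, 174, 6.11 and 7.07 CPM at passages 2, 3, 4, 6, 10 and 22 of series 1. In series 2 it had 304, 32.9, 2.71 and 3.02 CPM at passages 1, 5, 10 and 22, the last in the ESC-like library. The 3 MEF_ciHep libraries had 110, 406 and 1060 CPM of the placental gene Prl3d1 and 11800, 2880 and 4400 CPM of the stomach gene Gkn1.

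Of the tests that follow, the one of implied length was chosen after the result was seen, and the others were fixed before. In a further pattern, chromosome 1 genes read higher in 4 MEF_ciEPC libraries than in passages 2, 3 and 4 of series 1, with median log2 shifts of 0.47 and 0.49 at passages 10 and 22 of series 1 and 0.39 and 0.35 at passages 5 and 10 of series 2. Medians of the other autosomes were −0.19 to 0.22. Against the same passages, MNF_ciEPC replicates 1 and 2 shifted by 0.16 and 0.19 on chromosome 5, 0.3 and 0.3 on chromosome 10, 0.37 and 0.27 on chromosome 13 and −0.26 and −0.28 on chromosome 14, with no explanation tested. A bias of GC content, transcript length or expression level is argued against, since matched genes off chromosome 1 shifted by at most 0.02. The implied length was 50.6 bases in these 4 libraries and series 2 passage 1 and 50.5 in the rest of MEF_ciEPC. A bias of this length stays open: series 2 passage 1 shifted by only 0.14 (0.09 to 0.17) but the rest by −0.06 to 0.06. An extra copy of the whole chromosome in part of the cells may explain it: the lowest median of 10 windows along the chromosome was 0.2 and the highest 0.69, with at least 7 genes in a window, and each chromosome median was under 0.58, the value of 1.5 copies to 1 on the log2 scale.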
